A study of Mus musculus with 24 samples.

How the data were processed

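The deposited files gave 1 list of peaks per library, with the summit of each peak, on mouse build GRCm38 (mm10). Reads had been aligned with BWA and peaks called with MACS2 according to the submitters' notes, and the versions and settings are not given in the sources used here. Each peak carried the authors' fold ratio over the local background, its -log10 p, its -log10 q and a score, all computed within 1 library. The lowest -log10 q of a list lay between 1.301 and 1.584. With the fold ratio and -log10 p read as the caller's usual formulas, the pileup at the summit came out as a whole number, within 0.01 in -log10 p, for 99.95% to 100% of 2000 peaks per library. The lists held no read counts, so the depth behind a single peak is unknown and no count-based test was used.

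Peaks on chromosomes 1 to 19 and X were ranked within each library by the authors' -log10 p, and 53 of the 586440 peaks lay elsewhere and were not used. The lists differed in length, so only the strongest peaks of each library were taken, the same number in every library of a fit. Each kept peak received a rank value, which is its quantile within the list: 1 for the strongest peak and near 0 for the weakest. A library without a kept peak over a region had a rank value of 0. A rank value therefore describes the order of peaks within a library and is not an amount of open chromatin. Regions of 501 bp were placed around the summits, strongest first, and kept when at least 2 libraries had a peak overlapping by 1 bp or more. Lists of fewer than 10000 peaks were left out of the fits. The tumor fit used 12 libraries, the strongest 19000 peaks of each and 27065 regions. The tissue fit used the DN, LAG3_SP and TDT_SP libraries of tumor and lymph nodes, in all 15 libraries, the strongest 14000 peaks and 22997 regions.

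Regions were compared with limma (lmFit and eBayes with a trend), and a region was called at a Benjamini-Hochberg adjusted p under 0.05 over all regions of its fit. All 4 tumor groups shared 1 fit, and the tissue fit carried the sorted subset as a covariate. The difference of a subset effect between tumor and lymph node was tested as an interaction, with the draining and non-draining nodes pooled. In that fit each lymph node group had 2 libraries or fewer per subset, and limma assumes that they vary like the other libraries. A difference is always the first group named minus the second, in units of rank value, and SE is the standard error of that difference. Nothing in the labels says that replicates came from separate animals, so every p-value measures only the spread between these libraries. In a self-test on simulated shifts, a shift of 0.3 in rank value was recovered in 27 of 100 regions and a shift of 0.6 in 70 of 100 for tumor DP minus DN, with 9 false calls among 27065 regions. For tumor minus lymph node the same shifts were recovered in 36 and 98 of 100 regions, with 7 false calls among 22997. The simulated noise was normal and independent between libraries. Real regions can have a rank value of 0 in every library of a group, and some real libraries deviated together. The recovery and the false calls of the simulation therefore need not hold for the real data.

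Each region was assigned to the nearest protein-coding gene interval within 100 kb, from a table of 21631 genes on build GRCm38. The plan had named the transcription start site, but the table held gene ends without strands or exons, so the nearest gene interval was used and positions are given as inside a gene or as a distance beyond its end. For the same reason the promoter share of the plan became the share of summits within 1 kb of an annotated gene end, and a planned motif share, which needs the genome sequence, was not run. Nearness does not show that a region regulates the gene.

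The comparisons, their tests, most alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Alternatives and tests of explanations that were chosen later are named as such where they are given. The 18 lists were exhaustion, naive and memory, progenitor exhausted, effector, T cell receptor (TCR) signal induced, tissue residency, lymphocyte egress and homing, chemokines and cytokines, interferon response, cell cycle, T cell identity, CD4 and Treg, NK and innate, B cell, myeloid, melanoma, stroma and endothelium, and housekeeping. They held 212 genes, of which 210 were in the gene table. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 18 lists, and again with an estimated correlation. Genes named in the text were 17 genes fixed in advance, up to 4 genes per list with the smallest p, and the genes with the most called regions, and the values of a gene are those of its region with the smallest p unless another is stated. Of the 17 genes, 1 is not reported here. Single values per library were compared with exact permutation tests over all arrangements of the group labels.

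All computations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.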

Results

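Chromatin accessibility was profiled by bulk Omni-ATAC, in which the transposase Tn5 inserts sequencing adapters into open chromatin, in CD8 T cells from mice with subcutaneous B16-F10 melanoma. The mice carried a tamoxifen-inducible Cre recombinase at Lag3 and a tdTomato reporter, so a cell that expressed Lag3 during tamoxifen treatment kept the red label afterwards. Tamoxifen (2 mg) was given on days 8 to 10 and tissue was taken on day 19. The series states as its purpose to follow accessibility as CD8 T cells become exhausted or memory-like. The 24 libraries formed 10 groups. From tumor there were 4 libraries of LAG3-negative tdTomato-negative cells (DN), 4 of LAG3-positive tdTomato-positive cells (DP), 3 named LAG3_SP and 3 named TDT_SP. The tumor-draining lymph node (DLN) and the non-draining node (NDLN) each gave 2 DN, 1 LAG3_SP and 2 TDT_SP libraries.

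The labels of the single-positive libraries conflict: the libraries named LAG3_SP are described as LAG3-negative and tdTomato-positive, and those named TDT_SP as tdTomato-positive without a LAG3 state. The groups are kept here by library name, and no LAG3 state is assumed for either of them.

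The lists held 586440 peaks in all, and 18 libraries had between 14244 and 48268 peaks each. The other 6 libraries had 301 to 6613 peaks and were not used in the fits: DLN DN replicate 2 (301 peaks), NDLN TDT_SP replicate 2 (321), DLN TDT_SP replicate 2 (3909), tumor DN replicate 3 (4603), tumor DP replicate 3 (5188) and NDLN DN replicate 2 (6613). Each tumor group thus kept 3 libraries, and each lymph node group kept 1.

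**Figure D1:**
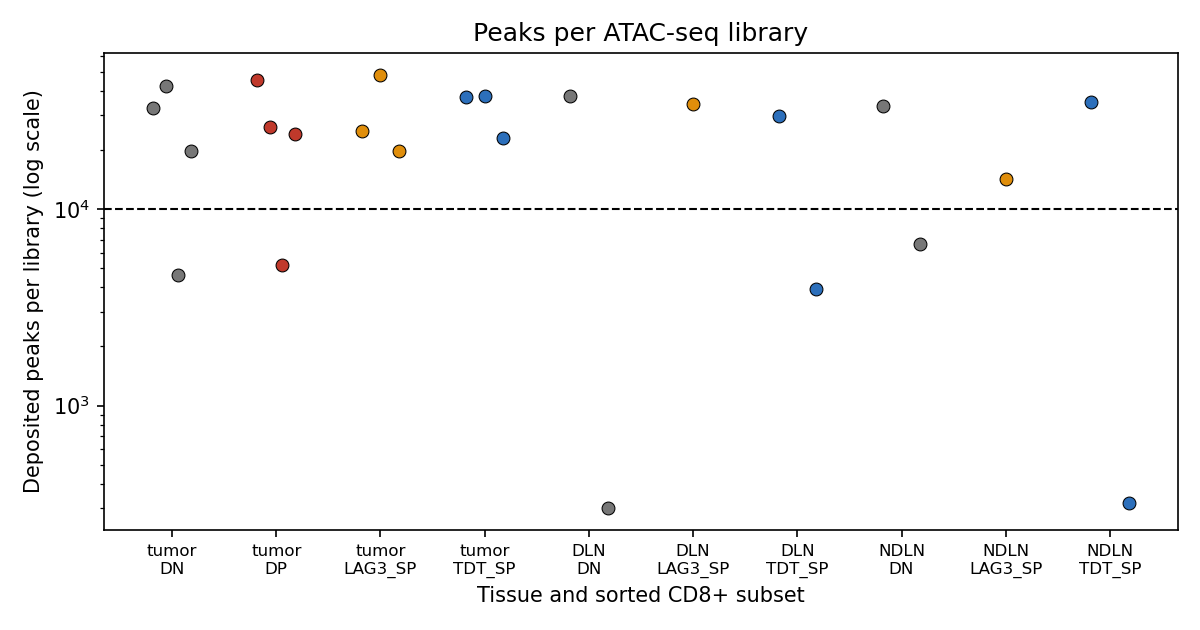
Number of deposited peaks in each of the 24 libraries (log axis), grouped by tissue and sorted subset, with 1 point per library. The dashed line marks 10000 peaks, and the 6 libraries under it, with 301 to 6613 peaks, were left out of the fits.

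Whether libraries of a sorted subset shared their strongest regions more than libraries of different subsets was asked in the 12 tumor libraries. The Jaccard index, the share of regions that a pair of libraries had in common, averaged 0.749 within groups and 0.699 between groups (exact permutation p = 0.00052 over 369600 arrangements). DN libraries overlapped least with LAG3_SP (0.639) and DP (0.667) and most with TDT_SP (0.735). DP overlapped about equally with LAG3_SP (0.728) and TDT_SP (0.733), and the DP libraries overlapped at 0.737 with each other. LAG3_SP and TDT_SP overlapped at 0.694. The LAG3_SP libraries overlapped at 0.704 with each other, with 0.648 and 0.7 in the pairs of replicate 3 and 0.763 in the other pair. The share of summits within 1 kb of an annotated gene end was 45.4% ± 2.04 in DN, 43.1% ± 2.25 in DP, 42.6% ± 3.88 in LAG3_SP and 44.1% ± 0.806 in TDT_SP (SD, n = 3 each; exact permutation p = 0.5445). With the strongest 4000 peaks of 14 libraries, DN and DP replicate 3 with short lists now included, it differed (exact permutation p = 0.01948), with 57.83% to 74.88% in LAG3_SP, 65.67% to 75.2% in DP, 76.58% to 82.12% in DN and 76.5% to 80.7% in TDT_SP.

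The comparison of DP with DN in tumor asked what distinguished cells with the tdTomato label and the LAG3 protein from cells with neither. The label marks only expression during tamoxifen treatment, so DN cells may have expressed Lag3 at another time. Among exhaustion genes, a region 22.28 kb beyond the end of Pdcd1 (1:94074586-94075086), which encodes the inhibitory receptor PD-1, had a rank value of 0.735 ± 0.023 in DP and 0.0714 ± 0.113 in DN (SD, n = 3; difference 0.664, SE 0.0926, adjusted p = 0.00212). A region 3.07 kb from Cd38, an ectoenzyme gene induced in dysfunctional T cells, was at 0.817 ± 0.11 in DP and 0.0297 ± 0.051 in DN (5:43915189-43915689, adjusted p = 0.000986). Regions near Ctla4, another inhibitory receptor gene, and inside Entpd1, which encodes the ectonucleotidase CD39, had no peak among the strongest 19000 in the 3 DN libraries and rank values of 0.568 ± 0.041 (adjusted p = 0.0228) and 0.547 ± 0.14 (adjusted p = 0.00226) in DP. A region inside Tox, whose product maintains the exhausted state, went the other way, from 0.442 ± 0.14 in DN to 0 in DP (adjusted p = 0.0459). The region next to Havcr2, which encodes TIM-3, was at 0.482 ± 0.094 in DP and 0 in DN and did not pass the test (adjusted p = 0.0506). In the exhaustion list 4 of 108 regions were higher in DP and 2 lower, 1 of the latter at Tox, and 5 were higher and 2 lower when adjusted over the list alone. For comparison with this and the other list counts, 708 of all 27065 regions were higher in DP and 371 lower. The list as a whole ranked higher in DP (camera adjusted p = 0.0236; adjusted p = 0.671 with an estimated correlation), but not without tumor DN replicate 4 (0.0647) or tumor DP replicate 2 (0.0515).

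Single regions near 3 transcription factor genes of effector cells were higher in DP. A region 59.52 kb from Id2 was at 0.91 ± 0.055 in DP and 0.362 ± 0.1 in DN (adjusted p = 0.00128), 1 of 11 regions near Prdm1, the gene of BLIMP1, rose by 0.617 (adjusted p = 0.0107), and a region inside Tbx21, the gene of T-bet, rose by 0.526 (adjusted p = 0.0216). A region 24.91 kb from Ifng, the main cytokine gene of cytotoxic T cells, was at 0.816 ± 0.032 in DP and 0.513 ± 0.062 in DN (adjusted p = 0.0166). In the effector list 5 of 99 regions were higher and 4 lower, 3 of the latter near Fasl, against 13 higher and 7 lower when adjusted over the list alone. The chemokine and cytokine list had 5 regions higher, among them 3 near Il10 and 1 near Xcl1, and 1 lower, near Il21 (13 and 1 when adjusted over the list alone). Camera called the chemokine and cytokine list (adjusted p = 0.000484) and the effector list (adjusted p = 0.0278), each at 0.671 with an estimated correlation. The effector call ended without tumor DN replicate 4 (0.09479) or tumor DP replicate 2 (0.111).

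Genes of naive, memory and progenitor cells moved in both directions. Regions near Ccr7, the receptor gene for lymph node entry, and Id3, a transcription factor gene of memory precursors, were at 0.317 ± 0.063 and 0.416 ± 0.12 in DN and had no kept peak in the 3 DP libraries (adjusted p = 0.003 and 0.00647). Regions inside Bach2 and Tcf7, the latter the gene of TCF1, were at 0.525 ± 0.012 and 0.514 ± 0.25 in DN and 0 in DP (adjusted p = 0.0075 and 0.0476). In contrast, a region 52.84 kb from Lef1 was at 0.955 ± 0.017 in DP and 0.73 ± 0.041 in DN (adjusted p = 0.00128), and a region inside Foxp1 was also higher in DP (difference 0.478, adjusted p = 0.0191). The naive and memory list had 3 regions higher and 4 lower of 104 (4 and 6 when adjusted over the list alone; camera adjusted p = 0.516). The progenitor exhausted list had 1 region higher, near Xcl1, and 2 lower, at Tcf7 and Id3, of 72 (2 and 4 when adjusted over the list alone; adjusted p = 0.988, with a mean difference of 0.00909 against a test direction of lower). The regions with the smallest p at Il7r (adjusted p = 0.973), Slamf6 (0.11), Gzmb (0.18), Cd8a (0.128) and Tigit (0.298) did not pass the test.

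Among the other lists, tissue residency had 3 of 60 regions higher, 2 of them near Rgs1 and 1 inside Runx3, and 1 lower, near Cd69 (camera adjusted p = 0.516). T cell identity had 2 regions higher and 1 lower of 95, with regions of both directions at Runx1 and a higher region inside Ets1 (0.719 ± 0.094 in DP and 0.17 ± 0.15 in DN; adjusted p = 0.563). Cell cycle had 1 region higher of 52, inside the kinase gene Cdk6 (0.836 ± 0.043 and 0.114 ± 0.2; list adjusted p = 0.563). The CD4 and Treg list had 2 higher of 16, inside Ikzf2 and inside Cd4 (list adjusted p = 0.161). Markers of other cell types each had 1 called region: higher inside Blk in the B cell list (list adjusted p = 0.425), higher 69.7 kb from Cebpb in the myeloid list (0.234) and lower near Klrb1c in the NK and innate list (0.902). TCR signal induced and lymphocyte egress and homing each had 1 lower region, at Cd69 and Ccr7 (0.563 and 0.386). None of the called regions lay in the interferon response, melanoma, stroma and endothelium or housekeeping lists (camera adjusted p = 0.563, 0.607, 0.988 and 0.988).

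Over the genome, 708 regions were higher in DP and 371 lower (limma, 27065 regions; 4985 at an unadjusted p under 0.05). The genes with the most higher regions were Ptprj, a receptor phosphatase gene (4 of 9), then Rgs13, Etv6 and Epas1 (3 each), and those with the most lower regions were Thada and Fasl (3 each, with 1 more region of each higher), then Abca1 and Jak1 (2 each). The count depended on single libraries: without tumor DP replicate 1 it was 357 higher and 144 lower, and in total it was 514 without tumor DP replicate 2 and 698 without tumor DN replicate 1. The balance turned without tumor DN replicate 4, with 558 higher and 786 lower. In a fit of the DN and DP libraries alone it was 21, and with all peaks of each library, or with the strongest 4000, it was 14, all higher. The calls named above at Pdcd1, Cd38, Entpd1, Id2, Ccr7, Id3, Bach2 and Lef1 held when each library was left out in turn, but all 8 were lost with all peaks of each library and in the fit of the DN and DP libraries alone. Those at Ctla4, Ifng, Prdm1, Tbx21, Foxp1, Tox, Tcf7, Cd69, Il10, Rgs1, Blk, Cd4, Xcl1, Fasl, Runx3, Klrb1c and Thada each ended without at least 1 library.

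**Figure D2:**
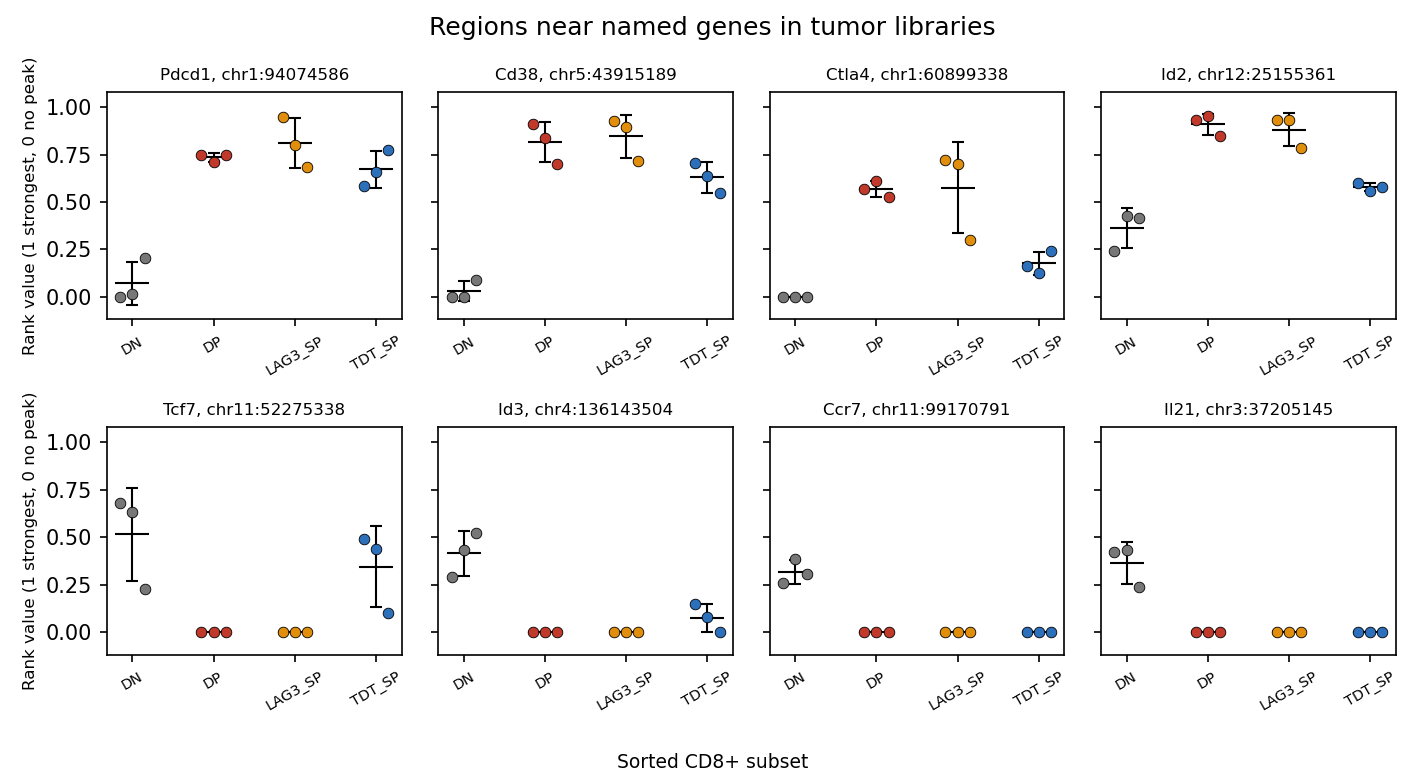
Rank value (1 for the strongest peak of a library, 0 for no peak among the strongest 19000) of 1 region each at Pdcd1, Cd38, Ctla4, Id2, Tcf7, Id3, Ccr7 and Il21 in the 4 tumor groups; points are libraries, and dashes with bars are the mean ± SD (n = 3). The Pdcd1 region was at 0.0714 in DN and between 0.672 and 0.812 in the other groups, and the Ccr7 region was at 0.317 in DN and 0 in the others.

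At Lag3, the gene that defines the groups, no region passed the test. Of its 8 regions, 0 were called by limma for DP minus DN and 0 had an unadjusted p under 0.05. The region with the smallest p (adjusted p = 0.618) was at 0.154 ± 0.159 in DP and 0.282 ± 0.247 in DN. Inside the gene itself, tumor TDT_SP replicate 3, tumor DN replicate 3 and tumor DP replicate 3 shared a block of 7 narrow peaks, of which the long-list DP libraries had at most 1. A region inside the neighboring gene Cd4 (6:124885114-124885614) had no peak among the strongest 19000 in DN and was at 0.472 ± 0.13 in DP and 0.409 ± 0.037 in LAG3_SP (adjusted p = 0.0166 and 0.0274), a call that DP minus DN lost without tumor DN replicate 1, tumor DN replicate 2 or tumor DP replicate 2.

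**Figure D3:**
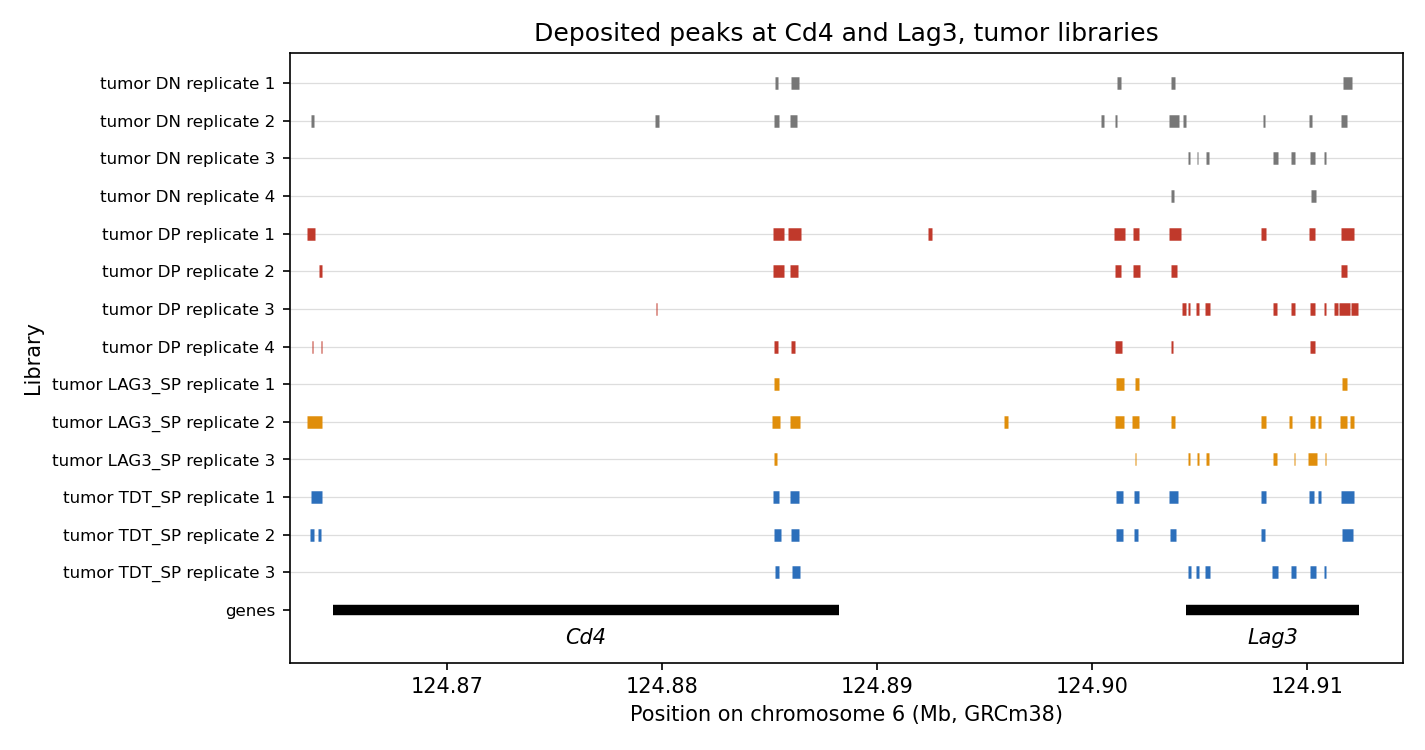
Deposited peaks of the 14 tumor libraries over Cd4 and Lag3 on chromosome 6 (position in Mb on the x axis, 1 line per library). Black bars at the bottom are the annotated gene intervals. The block of 7 peaks inside Lag3 is seen in tumor DN replicate 3, tumor DP replicate 3 and tumor TDT_SP replicate 3.

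LAG3_SP was compared with the same DN libraries, so its values share their controls with the comparison above. The Pdcd1 region was at 0.812 ± 0.13 (adjusted p = 0.00115), the Cd38 region at 0.846 ± 0.12 (adjusted p = 0.000836) and the Ctla4 region at 0.575 ± 0.24 (adjusted p = 0.0174, n = 3 each). At Entpd1 a different region inside the gene was higher than in DN (0.347 ± 0.089 against 0, adjusted p = 0.0293). The regions named above at 3 factor genes were also higher, with Id2 at 0.882 ± 0.086, Tbx21 at 0.773 ± 0.066 and Prdm1 at 0.681 ± 0.17 (adjusted p = 0.00119, 0.00917 and 0.0104). Ifng had 2 of 17 regions higher and Il10, the gene of an immunosuppressive cytokine, 3 of 8. Xcl1, a chemokine gene of cells that recruit dendritic cells, had 2 of 9 regions higher, 1 of them at 0.6 ± 0.091 against 0.0122 ± 0.015 in DN (adjusted p = 0.0068). Regions near Ahr and Ccr8, genes of tissue-resident cells, and Ccr2, a receptor gene for inflamed tissue, were higher (adjusted p = 0.0119, 0.0274 and 0.028). Regions at Ccr7, Id3 and Tcf7 had no kept peak in the 3 LAG3_SP libraries (adjusted p = 0.00256, 0.00534 and 0.0389), and the region inside Bach2 was at 0.026 ± 0.045 (adjusted p = 0.00853). Lef1 (0.954 ± 0.029, adjusted p = 0.00107) and Foxp1 (0.561 ± 0.021, adjusted p = 0.0143) were higher. Near Havcr2 the value was 0.431 ± 0.22 (adjusted p = 0.0642).

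In LAG3_SP minus DN, 4 lists were called by camera, each with an adjusted p of 0.278 with an estimated correlation. Chemokines and cytokines had 9 of 64 regions higher and 1 lower (adjusted p = 2.93e-05; 14 and 2 when adjusted over the list alone), exhaustion 6 of 108 higher and 2 lower (adjusted p = 0.000615; 9 and 2), and effector 9 of 99 higher and 1 lower (adjusted p = 0.000615; 14 and 6). CD4 and Treg had 2 of 16 higher, at Ikzf2 and Cd4 (adjusted p = 0.0272; 3 and 0), a call that ended without tumor DN replicate 1 (0.0513) or tumor LAG3_SP replicate 3 (0.13). Called regions also lay inside Cd226 and Klrc1 (NK and innate list), inside Blk and near Ebf1 (B cell list) and near Cebpb (myeloid list), and none of these 3 lists was called (adjusted p = 0.475, 0.107 and 0.187). In all, 976 regions were higher and 543 lower (6170 at an unadjusted p under 0.05), with the most at Etv6 (6 of 13 higher), Rgs13 and Kcnk10 (4 each), Thada and Pdlim1 (3 lower each). The total of 1519 was 823 without tumor LAG3_SP replicate 1, 921 without tumor DN replicate 1 and 2575 without tumor LAG3_SP replicate 3, and 0 in a limma fit of the LAG3_SP and DN libraries alone. It held more lower than higher regions, 946 against 750, without tumor DN replicate 4. Without at least 1 library, Ctla4, Entpd1, Tcf7, Cd4, Ccr8, Ccr2, Blk, Klrc1, Ebf1 and Pdlim1 lost the call.

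TDT_SP minus DN gave fewer calls, 57 regions higher and 97 lower (2556 at an unadjusted p under 0.05). The Pdcd1 region was at 0.672 ± 0.097 (difference 0.6, adjusted p = 0.00955) and the Cd38 region at 0.63 ± 0.08 (adjusted p = 0.00797, n = 3 each). The regions near Ccr7 and Il21, the gene of a helper cytokine, had no kept peak in the 3 TDT_SP libraries (adjusted p = 0.00815 and 0.0118), nor had regions at Cd69 and Smad7, a brake on TGF-beta signaling (adjusted p = 0.0467 and 0.00849). A region near Tet2, a DNA demethylase gene, was at 0.691 ± 0.037 against 0.0305 ± 0.053 in DN (adjusted p = 0.00298), and regions at Trib1, Stk39 and Dock2 were higher by 0.422, 0.546 and 0.587. Inside Taf5l a region was higher (0.7 ± 0.07 against 0.0321 ± 0.056, adjusted p = 0.00376). The higher regions inside Cflar, an inhibitor gene of death receptor signaling, and Itgb7 had differences of -0.0387 and -0.0145 when a peak was counted only where its summit lay inside the region. Regions with the smallest p at Id3 (0.0757 ± 0.074, adjusted p = 0.0569), Lef1 (adjusted p = 0.0539), Ctla4 (adjusted p = 0.126), Havcr2 (0.389), Entpd1 (0.436) and Tcf7 (0.647) did not pass. No list was called, with adjusted p = 0.0517 for both exhaustion (direction higher) and naive and memory (direction lower).

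The TDT_SP minus DN total of 154 ranged widely as libraries were left out. It was 67, 83 and 78 without tumor TDT_SP replicates 1, 2 and 3, 81 and 100 without tumor DP replicates 1 and 2, 99 and 88 without tumor LAG3_SP replicates 1 and 2, and 549 without tumor DN replicate 4. Higher regions outnumbered lower ones without tumor TDT_SP replicate 1 (36 and 31) or 2 (42 and 41), as presence or absence (243 and 160) and in the fit of the 2 groups alone (21 and 3). The call at Pdcd1 was lost without tumor TDT_SP replicate 3, those at Ccr7, Cd38 and Smad7 without tumor TDT_SP replicate 1, and that at Il21 without any 1 of the 3 TDT_SP libraries, while Tet2, Taf5l, Trib1, Stk39, Dock2, Jak1 and Abca1 held with each library left out. These 7 calls were lost with all peaks of each library and in the fit of the TDT_SP and DN libraries alone.

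The DP, LAG3_SP and TDT_SP groups of the tumor were then compared with each other. Between LAG3_SP and DP 0 regions were called in limma (1571 at an unadjusted p under 0.05), and none of the 18 lists. The Entpd1 region that was at 0.547 ± 0.14 in DP was at 0.0243 ± 0.042 in LAG3_SP (adjusted p = 0.188), and a region 3.63 kb from Pdcd1 was at 0.465 ± 0.053 in LAG3_SP and 0.0633 ± 0.057 in DP (adjusted p = 0.528). The count of 0 became 53 without tumor LAG3_SP replicate 3, 21 without tumor DP replicate 4, 18 without tumor LAG3_SP replicate 2 and 1 without tumor DN replicate 4.

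In TDT_SP minus DP, 5 regions were higher, at Taf5l, Zfp523, Ubxn4, Cflar and Ms4a8a, and 4 lower, at Entpd1, Cd47, Arl14ep and Nt5e (3158 at an unadjusted p under 0.05). The Cflar difference became -0.0194 when a peak was counted only where its summit lay inside the region. Entpd1 and Nt5e encode the pair of ectoenzymes that turn extracellular ATP into adenosine. The Entpd1 region had no kept peak in TDT_SP (adjusted p = 0.04), and the Nt5e region was at 0.462 ± 0.053 in TDT_SP and 0.92 ± 0.02 in DP (adjusted p = 0.0482, n = 3 each). The region near Cd47, the gene of a signal against phagocytosis, fell from 0.955 ± 0.025 in DP to 0.538 ± 0.082 (adjusted p = 0.0286). A region 30.9 kb from Tcf7 was at 0.627 ± 0.039 in TDT_SP and 0.0984 ± 0.17 in DP (adjusted p = 0.181), and the Ifng and Ctla4 regions were lower by 0.248 and 0.391 without passing (adjusted p = 0.165 and 0.255). The chemokine and cytokine list ranked lower in TDT_SP (camera adjusted p = 0.0276; 0.742 with an estimated correlation), although none of the 9 called regions lay in the list and none was added when adjusted over the list alone. That list call ended without tumor DP replicate 2 (0.518), tumor TDT_SP replicate 1 (0.0673) or tumor TDT_SP replicate 3 (0.0809). The total of 9 was 0 without tumor DN replicate 1, tumor DP replicate 2, tumor LAG3_SP replicate 1 or tumor LAG3_SP replicate 2. It was 1 without tumor DN replicate 4, 2 without tumor DN replicate 2 or tumor DP replicate 1, 14 without tumor TDT_SP replicate 1, 20 without tumor TDT_SP replicate 3, 25 (4 higher, 21 lower) without tumor DP replicate 4 and 40 (10 higher, 30 lower) without tumor LAG3_SP replicate 3. Each of the 9 calls ended in at least 4 of these fits.

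LAG3_SP minus TDT_SP called 191 regions higher and 64 lower (4732 at an unadjusted p under 0.05). Regions near Xcl1 (0.6 ± 0.091 against 0.0615 ± 0.11, adjusted p = 0.0374), Rgs1, a regulator gene of chemokine receptor signaling (0.511 ± 0.13 against 0, adjusted p = 0.0347), and Il21 (0.456 ± 0.078 against 0.0179 ± 0.031, adjusted p = 0.0412) were higher in LAG3_SP. The Il21 region shown in the plot of rank values (3:37205145-37205645) was a different one. It was at 0 in every LAG3_SP and TDT_SP library of the tumor fit. The most higher regions lay near Rgs13 and Fam3c (3 each), then Kcnk10 and Pde4b (2 each), and single regions near Cd47, Arl14ep and Nrp1 were higher as well. Lower regions lay inside Cflar and Chd3 (2 each), Taf5l and Itgb7, where the Itgb7 difference became 0.0132 when only summits counted, and near Klra8. Ifng (difference 0.276, adjusted p = 0.0573), Entpd1 (adjusted p = 0.0687), Pdcd1 (0.0793) and the Tcf7 region at 0.627 ± 0.039 in TDT_SP and 0.114 ± 0.2 in LAG3_SP (adjusted p = 0.0928) did not pass. This Pdcd1 value is not from the region 22.28 kb beyond the gene end, which had a limma adjusted p of 0.451. The chemokine and cytokine list ranked higher in LAG3_SP (camera adjusted p = 0.00229; 0.528 with an estimated correlation), with 2 regions higher and 3 when adjusted over the list alone, and this call ended without tumor LAG3_SP replicate 1 (0.186). The total of 255 rested on single libraries. It was 0 without tumor LAG3_SP replicate 1, and without any 1 TDT_SP library the balance turned: 8 higher and 24 lower without replicate 1, 1 and 5 without replicate 2, and 10 and 16 without replicate 3. The total was 54 and 64 without tumor DN replicates 1 and 2, 143 without tumor DP replicate 1 and 829 without tumor LAG3_SP replicate 3.

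The comparison of tumor with lymph node, over the 9 tumor and 6 node libraries of DN, LAG3_SP and TDT_SP cells, asked how the tissue relates to accessibility. Genes of naive and memory cells ranked lower in tumor. A region inside Bach2, a repressor gene that holds T cells in the naive or memory state, was at 0.0735 ± 0.11 in tumor (n = 9) and 0.628 ± 0.11 in nodes (n = 6; adjusted p = 0.000619), and 6 of its 22 regions were lower and 2 higher. S1pr1, which encodes the receptor for leaving tissue, had 5 of 12 regions lower, 1 at 0.184 ± 0.22 against 0.819 ± 0.092 (adjusted p = 0.000771), and 2 higher. Ccr7 had 3 of 4 regions lower (0.0249 ± 0.056 against 0.527 ± 0.27 at 1 of them, adjusted p = 0.0013), Tcf7 3 of 7, Lef1 2 of 12, Foxp1 6 of 17, and Il7r, the gene of the interleukin-7 receptor, 1 of 2. Of the progenitor list, Cd28 had 6 of 9 regions lower and Cxcr5, a follicle homing receptor gene, 1 of 4 (adjusted p = 0.00166 and 0.00258 at the strongest). At Cxcr4 4 of 8 regions were lower. The naive and memory list had 36 of 108 regions lower and 4 higher (43 and 4 when adjusted over the list alone; camera adjusted p = 4.4e-06), progenitor exhausted 17 of 59 lower and 1 higher (20 and 3; 0.0203), and lymphocyte egress and homing 13 of 36 lower and 3 higher (14 and 3; 0.03), each at an adjusted p of 0.46 with an estimated correlation.

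Single regions of cytotoxic and cytokine genes ranked higher in tumor. A region 0.06 kb from Gzmb, the gene of granzyme B, was at 0.479 ± 0.17 in tumor and 0.0182 ± 0.045 in nodes (adjusted p = 0.0023). Ifng had 3 of 12 regions higher, 1 at 0.567 ± 0.17 against 0.108 ± 0.22 (adjusted p = 0.00236), Klrg1, a marker of terminal effector cells, 2 of 6, and Itga1, an integrin gene of resident cells, 3 of 6. Tnfsf10, which encodes the death ligand TRAIL, had 1 of 3 regions higher, and Il21 2 of 4 lower. Among cell cycle genes Top2a was at 0.813 ± 0.072 against 0.29 ± 0.27 (adjusted p = 0.000604), both regions of Birc5 were higher, and 8 of 42 regions of the list were higher and 3 lower (camera adjusted p = 0.306). The chemokine and cytokine list was called as higher in tumor (9 regions higher, 3 lower; 11 and 3 when adjusted over the list alone; camera adjusted p = 0.0159; 0.46 with an estimated correlation), and the effector list was not (11 higher, 6 lower; 0.208).

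Genes of exhaustion and activation went both ways between tumor and nodes. The Pdcd1 region 22.28 kb beyond the gene end was at 0.433 ± 0.353 in tumor and 0.0121 ± 0.0297 in nodes (adjusted p = 0.0148), whereas a region 26.7 kb beyond it fell to 0.376 ± 0.246 from 0.787 ± 0.13 in nodes (1:94079008-94079508, adjusted p = 0.00266). Tox had 3 of 12 regions lower in tumor, 1 of them with a mean of 0.596 ± 0.38 in nodes and 0.00019 ± 0.00057 in tumor (adjusted p = 0.00201), and Ctla4 had 1 region higher and 2 lower. Cd69, an early activation gene, had 8 of 9 regions lower, Nr4a1 1 of 4 and Nr4a3 3 of 6, both of the latter being immediate targets of T cell receptor signals, while Tnfrsf9, which encodes the costimulator 4-1BB, had 1 of 7 higher. Cblb and Trio had 7 lower regions each and Rgs1 had 3. The exhaustion list had 9 of 86 regions higher and 9 lower (camera adjusted p = 0.801), TCR signal induced 4 and 13 of 79 (0.284), and tissue residency 6 and 13 of 48 (0.801). For comparison, 2346 of all 22997 regions were higher and 2769 lower, so both directions were common among all regions as well. Of the markers of other cells, a region inside Pmel, a pigment cell gene, was at 0.281 ± 0.22 in tumor and 0.000119 ± 0.00029 in nodes (adjusted p = 0.0362), a region inside Blk was at 0.443 ± 0.26 and 0 (adjusted p = 0.00548) and a region near Cebpb was higher (adjusted p = 0.0299). None of the melanoma, B cell and myeloid lists was called (adjusted p = 0.891, 0.92 and 0.194).

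In total 2346 regions were higher in tumor and 2769 lower (limma, 22997 regions, with 8856 at an unadjusted p under 0.05). The total of 5115 was 2131 with all peaks of each library and 1639 as presence or absence. With the replicate number as a block it was 282 (150 higher, 132 lower), but all node libraries of the fit carry the number 1, which ties tissue to that number. The progenitor exhausted call ended without NDLN LAG3_SP replicate 1 (0.0602) or tumor LAG3_SP replicate 3 (0.0595). The lymphocyte egress and homing call ended without DLN DN replicate 1 (0.0574), NDLN LAG3_SP replicate 1 (0.248), tumor LAG3_SP replicate 3 (0.0739) or tumor TDT_SP replicate 3 (0.05021), and that of the chemokine and cytokine list without DLN LAG3_SP replicate 1 (0.156). Among the genes named here, Entpd1 (1 of 5 regions higher), Lef1, Tnfrsf9, Cebpb and Pmel lost the call without at least 1 library.

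The draining and non-draining nodes were compared with 3 libraries each, 1 per subset. In DLN a region inside the clock gene Arntl (0.336 ± 0.03 against 0, adjusted p = 0.0116), 1 near the lactate transporter gene Slc16a1 (0.419 ± 0.098 against 0.000167 ± 0.00029, adjusted p = 0.0116) and regions inside Tnni1 and Samd4 were higher (SD, n = 3). Regions inside Slc9a9 and Ankrd44 and a region near Rhoh, a gene needed for T cell receptor signaling, were lower (adjusted p = 0.0274, 0.0299 and 0.0402). Regions with the smallest p at Ctla4 (0.276 ± 0.23 in DLN and 0.668 ± 0.24 in NDLN, adjusted p = 0.538), Lef1 (adjusted p = 0.517) and Pdcd1 (0.879) did not pass. Camera ranked 3 lists lower in DLN, namely effector and T cell identity (both adjusted p = 0.0108) and exhaustion (0.0206), each at 0.576 with an estimated correlation. None of the 7 called regions lay in these lists. When adjusted over the list alone, exhaustion had 1 region higher, against the direction of the list, T cell identity had 1 lower and effector had none.

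All of these calls between the nodes depended on single libraries. Without DLN LAG3_SP replicate 1 the adjusted p was 0.82 for effector, 0.82 for T cell identity and 0.877 for exhaustion. Without NDLN LAG3_SP replicate 1 it was 0.0557, 0.675 and 0.0581 in the same order, and for exhaustion it was 0.114 without NDLN DN replicate 1 and 0.08127 without NDLN TDT_SP replicate 1. The total of 7 called regions (1543 at an unadjusted p under 0.05) was 73, 56 and 31 without the DN, LAG3_SP and TDT_SP replicate 1 of DLN and 44, 35 (6 higher, 29 lower) and 17 (5 higher, 12 lower) without those of NDLN. It was 0 without tumor TDT_SP replicate 1 or 2, and 2 without tumor TDT_SP replicate 3, tumor DN replicate 1, 2 or 4, or tumor LAG3_SP replicate 1 or 2. Each of the 7 named regions lost its call in at least 1 of these fits.

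Whether the subset effects differed between tumor and lymph node was tested as an interaction, and a positive value means that the subset stood higher over DN in tumor than it did in nodes. For LAG3_SP minus DN, 1452 regions had a positive and 507 a negative interaction (4783 at an unadjusted p under 0.05), and for TDT_SP minus DN 835 and 181 (2836). In nodes alone, LAG3_SP minus DN gave 752 regions higher and 1876 lower in limma, and TDT_SP minus DN gave 531 and 1312. A positive interaction can thus come from a lower value than DN in nodes, without a gain over DN in tumor. The Pdcd1 region 22.28 kb beyond the gene end was at 0.746 ± 0.18 in tumor LAG3_SP, 0.554 ± 0.13 in tumor TDT_SP and 0 in tumor DN (n = 3 each), and at 0 in 5 of the 6 node libraries and 0.0727 in NDLN TDT_SP (interaction adjusted p = 0.0137 for LAG3_SP and 0.125 for TDT_SP). The Cd38 region had a positive interaction for LAG3_SP (0.786, SE 0.151, adjusted p = 0.00606), as had regions near Id2, Xcl1 and Cx3cr1. A region 33.6 kb from Ctla4 was at 0.439 ± 0.094 in tumor LAG3_SP, 0.407 ± 0.031 in tumor TDT_SP and 0 in DN and in all node libraries (adjusted p = 0.0176 and 0.0383).

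Regions open mainly in the 2 node DN libraries were among the positive interactions. A region inside Bach2 was at 0.528 in DLN DN and 0.672 in NDLN DN and at 0 in every other group (adjusted p = 0.000138 for LAG3_SP and 0.000142 for TDT_SP). Regions at Lef1 and Il2, the gene of a growth factor of T cells, were at 0.448 and 0.534 and at 0.483 and 0.509 in these 2 libraries and at 0.0463 or less elsewhere. Further positive regions lay near Prkcq, a kinase gene of the T cell receptor pathway (7 regions for LAG3_SP), near Prag1 (6 for TDT_SP), near Eomes and Cd28 for TDT_SP, and at Tox and Klrd1 for both. In nodes alone, Prkcq had 8 lower regions for LAG3_SP minus DN and Prag1 had 6 for TDT_SP minus DN. Negative ones included a region inside Foxp1 found only in node TDT_SP libraries (0.643 and 0.522, adjusted p = 0.000118), 2 regions of St6gal1 for TDT_SP and 2 of Nr4a1 for LAG3_SP. None of the 18 lists was called in either interaction (lowest adjusted p = 0.12 and 0.84). The LAG3_SP total of 1959 was 1294 without DLN DN replicate 1 and 1182 without NDLN DN replicate 1. The 507 negative regions became 1000 (1367 positive) without NDLN LAG3_SP replicate 1 and 933 (1848 positive) without DLN LAG3_SP replicate 1, and 239 and 315 without NDLN and DLN DN replicate 1. They were 317, 310 and 320 without tumor DN replicates 1, 2 and 4, and 334 without tumor TDT_SP replicate 1. For TDT_SP the 181 negative regions became 303 and 291 without DLN and NDLN LAG3_SP replicate 1, 284 without NDLN TDT_SP replicate 1, 117 without NDLN DN replicate 1 and 113 to 115 without any 1 tumor TDT_SP library. The Pdcd1 and Ctla4 calls for LAG3_SP ended without either of the node DN libraries. The calls at Cx3cr1 for LAG3_SP and at Ctla4 and Cd28 for TDT_SP also ended without at least 1 library.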

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

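The tests on narrow-peak libraries, on the libraries outside the fits, on the long-list DP libraries at Lag3, on Zbtb7b and on other splits of the samples were chosen after the results were seen.

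The first pattern is the set of 1079 regions that differed between tumor DP and DN. These regions were also looked up outside the fit: at an equal list length of 4603 peaks, tumor DP replicate 3 covered 177 of the 708 higher regions (25.0%) and tumor DN replicate 3 covered 21 (2.97%). Of the 371 lower regions they covered 6 (1.62%) and 16 (4.31%). Among their strongest 4000 peaks, 71.85% and 80.75% of summits lay within 1 kb of a gene end. The lists thus differed in kind, and the coverage has no baseline over all regions. Both libraries had been left out for their short lists, and with 1 library per group this pair cannot decide whether the difference holds beyond the libraries of the fit. The number of peaks in the lists is argued against as the cause, since 1123 regions were called with it as a covariate. Without the libraries with narrow peaks 1909 regions were called. Among DN and DP libraries these were tumor DN replicate 4 (narrowest peak 74 bp) and tumor DP replicate 4 (72 bp). Both sides lost a library, so this count cannot decide whether narrow peaks caused a difference between the groups. The sorting of cells by LAG3 and tdTomato stays open as the cause, as do particular libraries, and a difference in the state of the mice between groups was not tested.

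The second pattern is a block of 7 narrow peaks inside Lag3 (6:124904450-124910900), which came to notice because tumor DN replicate 3, a library of LAG3-negative cells outside the fits, held all 7. So did tumor DP replicate 3 and tumor TDT_SP replicate 3, while LAG3_SP replicate 3 of the tumor had 4, DLN TDT_SP replicate 2 had 3 and each of the other 19 libraries had 2 or fewer. None of the 3 long-list libraries of LAG3-positive tumor DP cells had more than 1 of these peaks. A match required both ends within 50 bp, which the wide peaks of DP replicates 1 and 2 (median 383 and 388 bp) could rarely meet. These matches therefore cannot decide whether open chromatin of cells that express Lag3 caused the whole block. With peaks of any width, DP replicates 1, 2 and 4 had 3, 1 and 1 inside Lag3. DNA from another source than chromatin, such as a transgene or plasmid, stays open, as does a mapping or preparation artifact. Very strong peaks were not confined to Lag3: the best peak inside Camk2b ranked 1 to 3 in each library with 3 or more block peaks. It also ranked 2 in DLN DN replicate 2, which lacked the block, and 115 or weaker in the other libraries that had one. Ifngr1 ranked 1 to 18 in the block libraries except tumor TDT_SP replicate 3 (9215), and 1 in DLN DN replicate 2. Thy1 ranked 1 to 27 in the block libraries except tumor LAG3_SP replicate 3 (983). Il2 ranked 16 to 92 in them except tumor TDT_SP replicate 3 (11769). In the short list of DLN DN replicate 2, Thy1 ranked 50 and Il2 ranked 84. Foxp3 varied, from 8 in DLN TDT_SP replicate 2 to 1438 in tumor DN replicate 3 and no peak in tumor TDT_SP replicate 3. Tumor LAG3_SP replicate 3 and TDT_SP replicate 3 were used in the fits. The 100 strongest peaks of tumor DN replicate 3 recurred a median of 35 times among the strongest 1000 of the other libraries with the block, against 34 in NDLN DN replicate 2, a low-enrichment library without it; this met the written prediction by 1, but the range of 2 to 50 is too wide to count it as met.

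The third pattern is the region inside Cd4 that was higher in tumor DP than in DN by 0.472 (SE 0.0967). CD4 T cells in the sort are a candidate explanation, and the region at the end of Zbtb7b, a gene these cells need, differed by 0.0303 (SE 0.154, adjusted p = 0.968). Zbtb7b was already at 0.397 in DN and at 0.428 in DP, a baseline that could hide a small share of cells, so this explanation and accessibility of the Cd4 locus in CD8 cells cannot be told apart.

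The median pileup at summits of tumor DP replicate 1 was 31, far from 13 to 15 in the other 3 DP libraries (gap over range 0.889); 28 such tests were run and chance marks about 1 in 20 groups. The subset effects differed between tumor and lymph node by the interaction test in 1016 regions for TDT_SP minus DN and in 1959 for LAG3_SP minus DN.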

How the results depend on the processing

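The alternatives without the narrow-peak libraries, with a peak width covariate and with a peak number covariate, and leaving out libraries for the interactions, the gene-end share and the similarity, were chosen after seeing the data. Every other alternative here was planned. Unless a reason is given, the cause was not tested.

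All counts here are regions called by limma, in the order of the main counts: 1079 for tumor DP minus DN, 1519 for LAG3_SP minus DN, 154 for TDT_SP minus DN, 0 for LAG3_SP minus DP, 9 for TDT_SP minus DP, 255 for LAG3_SP minus TDT_SP, 5115 for tumor minus lymph node and 7 for DLN minus NDLN. The counts at an unadjusted p under 0.05 are in the report. Only counts that moved by more than 1.5 times are given, apart from DP minus DN with the replicate block and the ranges over left-out libraries.

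With 0.5 times the number of peaks per library, DP minus DN gave 228, LAG3_SP minus DN 345, TDT_SP minus DN 4, LAG3_SP minus TDT_SP 70, tumor minus lymph node 2135 and DLN minus NDLN 1. The interactions gave 545 for TDT_SP and 1077 for LAG3_SP. With all peaks of each library the counts were 14, 12, 0 for TDT_SP minus DN, 0 for TDT_SP minus DP, 0 for LAG3_SP minus TDT_SP, 2131 for tumor minus lymph node and 0 for DLN minus NDLN. With libraries of 4000 peaks or more and the strongest 4000 peaks of each, which brings back short lists, they were 14, 23, 0, 1 for LAG3_SP minus DP, 0 for TDT_SP minus DP, 8 for LAG3_SP minus TDT_SP, 1114 and 2. Ranked by fold, they were 352, 526, 46, 0 for TDT_SP minus DP, 0 for LAG3_SP minus TDT_SP, 3134 and 3. With a -log10 q of at least 5, they were 426, 648, 35, 114 for LAG3_SP minus TDT_SP and 29 for DLN minus NDLN (6 higher, 23 lower).

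As presence or absence, TDT_SP minus DN gave 403 with the balance turned (243 higher, 160 lower), LAG3_SP minus DP 81, TDT_SP minus DP 215 (75 higher, 140 lower), tumor minus lymph node 1639 and DLN minus NDLN 34. With regions of any number of libraries, LAG3_SP minus DP gave 6, TDT_SP minus DP 38 (15 higher, 23 lower) and DLN minus NDLN 17, and with regions in 3 or more libraries DLN minus NDLN gave 3. With the summit inside the region TDT_SP minus DP gave 0. In that setting 4 named differences reversed: Itgb7 in TDT_SP minus DN (-0.01446) and LAG3_SP minus TDT_SP (0.01316), and Cflar in TDT_SP minus DN (-0.03867) and TDT_SP minus DP (-0.01942). The cause of the reversals was not tested.

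With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, the counts were 21 for DP minus DN, 0 for LAG3_SP minus DN, 24 for TDT_SP minus DN (21 higher, 3 lower), 0 for TDT_SP minus DP and 20 for LAG3_SP minus TDT_SP (4 higher, 16 lower). Without the narrow-peak libraries they were 1909, 2814, 515, 50 for LAG3_SP minus DP, 1186 for LAG3_SP minus TDT_SP, 1 for DLN minus NDLN and 3045 for the LAG3_SP interaction. With the peak width covariate they were 2865 for LAG3_SP minus DN, 51 for TDT_SP minus DP (15 higher, 36 lower), 1650 for LAG3_SP minus TDT_SP and 2 for DLN minus NDLN. With the peak number covariate they were 5 for TDT_SP minus DP, 166 for LAG3_SP minus TDT_SP and 2 for DLN minus NDLN.

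With the replicate number as a block, TDT_SP minus DN gave 22, TDT_SP minus DP 0, LAG3_SP minus TDT_SP 6 (1 higher, 5 lower), tumor minus lymph node 282 (150 higher, 132 lower) and DLN minus NDLN 0, and DP minus DN gave 1151. All 6 node libraries of the fit carry the number 1, so the block ties tissue to that number. The numbers were not taken to pair the libraries, since the labels do not say what they mark and 7 of the 14 pairs with the same number had a residual correlation over 0.1 (0.0271 to 0.268, median 0.102). The 40 other pairs ranged from -0.251 to 0.333 (median -0.127), and 2 of 12 libraries correlated best with one of their own number. A batch is not excluded: DN 4, DP 4, LAG3_SP 3 and TDT_SP 3, 1 library of each tumor group, correlated with each other at 0.187 to 0.333 and negatively with all other libraries of other groups. Deviations from a group mean cancel out within the group, so the negative values follow in part from the positive values. These 4 libraries had the fewest peaks of their groups in the fit (19771, 24050, 19679 and 22994). List length and a batch therefore cannot be told apart here. The 4 tumor libraries numbered 3 also had 4 to 7 peaks of the block inside Lag3 each, and no other tumor library had more than 1.

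The gene-end share passed with the strongest 4000 peaks (exact p = 0.01948), where it was lowest in LAG3_SP, and had an exact p of 0.05461 with 0.5 times the number of peaks. With an estimated correlation none of the called lists passed: adjusted p = 0.6713 for DP minus DN, 0.2778 for LAG3_SP minus DN, 0.7423 for TDT_SP minus DP, 0.5284 for LAG3_SP minus TDT_SP, 0.4599 for tumor minus lymph node and 0.5764 for DLN minus NDLN. With regions within 20 kb of a gene, which are fewer, the adjusted p was 0.403 and 0.07294 for effector in DP and LAG3_SP minus DN, 0.1606 for CD4 and Treg in LAG3_SP minus DN, 0.2583 for chemokines and cytokines in TDT_SP minus DP, and 0.1548 for egress and homing in tumor minus lymph node, which was 0.2138 with regions over 1 kb from a gene end.

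With each library left out in turn, DP minus DN ranged from 5.0e2 (rounded; 357 higher and 144 lower, without tumor DP replicate 1) to 1426, LAG3_SP minus DN from 823 to 2575, TDT_SP minus DN from 67 to 549, LAG3_SP minus DP from 0 to 53, TDT_SP minus DP from 0 to 40, LAG3_SP minus TDT_SP from 0 to 829, tumor minus lymph node from 3521 to 5671 and DLN minus NDLN from 0 to 73. The interactions ranged from 695 to 1294 for TDT_SP and from 1182 to 2781 for LAG3_SP. The exact p ranged from 0.09935 to 0.8305 for the gene-end share and from 0.0002597 to 0.008182 for the similarity.

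The adjusted p of the called lists ranged, in DP minus DN, from 0.01374 to 0.06472 for exhaustion, 0.01471 to 0.1109 for effector and 0.0002499 to 0.0102 for chemokines and cytokines. In LAG3_SP minus DN it ranged from 4.623e-05 to 0.009578 for exhaustion, 0.000112 to 0.01084 for effector, 7.248e-07 to 0.002466 for chemokines and cytokines and 0.009911 to 0.1302 for CD4 and Treg. For chemokines and cytokines it ranged from 0.006876 to 0.5183 in TDT_SP minus DP, 3.013e-05 to 0.1856 in LAG3_SP minus TDT_SP and 0.003682 to 0.1558 in tumor minus lymph node. There it also ranged from 3.229e-07 to 2.012e-05 for naive and memory, 0.007554 to 0.06017 for progenitor exhausted and 0.007554 to 0.2478 for egress and homing. In DLN minus NDLN it ranged from 0.004503 to 0.8774 for exhaustion, 0.00319 to 0.8196 for effector and 0.001909 to 0.8196 for T cell identity.

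Of the values for called regions of named genes, 1981 kept direction and call with a library left out and 395 lost the call; in the other alternatives 1270 kept both, 778 lost the call and 4 reversed. Short lists had a median fold of 6.36 to 13.75 in their strongest 300 peaks, against 15.4 to 24.4 in the longer ones, so what can be seen in them is limited. The motif share and its alternatives were not run, because no genome sequence was used here.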

Other observations

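The tests on other splits of the samples were chosen after the results were seen, and the coverage values below were also chosen after seeing the data and have no test.

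The regions that differed between tumor DP and DN were looked up in the lymph node libraries, none of which was in the tumor fit, at an equal list length of 14243 peaks. Of the 708 higher regions, DLN DN replicate 1 covered 59 (8.33%) and NDLN DN replicate 1 covered 68 (9.6%). The LAG3_SP and TDT_SP node libraries covered more: 188 (26.6%) in DLN LAG3_SP, 203 (28.7%) in DLN TDT_SP, 210 (29.7%) in NDLN TDT_SP and 407 (57.5%) in NDLN LAG3_SP. Of the 371 lower regions, the DN libraries covered 316 (85.2%) in DLN and 313 (84.4%) in NDLN. DLN LAG3_SP covered 291 (78.4%), DLN TDT_SP and NDLN TDT_SP each covered 280 (75.5%), and NDLN LAG3_SP covered 147 (39.6%). There is 1 library per group, and NDLN LAG3_SP had the shortest list among them, 14244 peaks with a narrowest peak of 67 bp.

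At the region 26.71 kb beyond Pdcd1 in the tumor fit (1:94079011-94079511), the rank value was 0.72 ± 0.0631 in DN, 0.3 ± 0.302 in DP, 0.295 ± 0.243 in LAG3_SP and 0.534 ± 0.0438 in TDT_SP (SD, n = 3), with adjusted p = 0.159, 0.127 and 0.832 against DN.

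The 6 libraries of each pair of tumor groups make 10 splits into 3 and 3, too few for a share under 0.05. For DP minus DN 1 of the 10 splits, the real one, gave 1079 regions, and the highest other gave 4. The corresponding numbers were 1 split, 1519 and 11 for LAG3_SP minus DN, 1 split, 154 and 5 for TDT_SP minus DN, 1 split, 9 and 5 for TDT_SP minus DP, and 1 split, 255 and 0 (limma, against 4732 at an unadjusted p under 0.05 in the real split) for LAG3_SP minus TDT_SP. For LAG3_SP minus DP all 10 splits gave at least the real 0, and the highest gave 36. For DLN minus NDLN 6 of the 10 splits gave at least the real 7 regions. The highest other gave 153, which points to a structure of these samples. That split and those with 35, 75 and 88 regions set 2 libraries of a subset on the same side, while the 3 other splits with 1 library of each subset on each side gave 12 regions at most. For tumor minus lymph node 1 of 100 splits, the real one, gave 5115 regions and the highest other gave 2. The real count thus stood apart from random assignments of these libraries to tissue within each subset. The splits treat the libraries as exchangeable, and all 6 node libraries carry the replicate number 1. They therefore cannot separate the tissue from a batch tied to it, and the count was 282 with the replicate number as a block.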
